A study of Drosophila melanogaster with 10 samples.

How the data were processed

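Transcript levels were measured on 10 oligonucleotide arrays of 14010 probe sets, each hybridised with RNA from the heads of nonvirgin Drosophila melanogaster females of 3 to 5 days, with 100 to 200 heads per sample. The deposited values are intensity on a linear scale, 1 value per probe set and array, and the software, version and settings with which the authors made them are not given in the sources used here. The values themselves show that each array had been scaled to a common level before deposit, since the 2% trimmed mean lay at 500.1 on every array, and that they were neither log transformed nor brought to one distribution. The number of arrays limits the precision, and no background reading per probe set was used.

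Groups were taken from the labels. The parental strains Fr and Z30 had 2 arrays each, and the 6 chromosome substitution lines had 1 array each, so no line could be tested on its own. The letters of a line's name give the origin of the first (X), the second and the third chromosome, Z for Z30 and M for Fr, and the origin of the fourth chromosome and of the mitochondria is not labelled. Nothing in the labels says that the 2 arrays of a parent came from separate cultures, so p-values measure at most the spread between these arrays, which may be technical.

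The deposited scaling was kept, values under the pooled 20th percentile of the 10 arrays (a signal of 38.9) were set to that floor, and log2 was taken. A probe set at the floor on every array of a group has only a bound there, and its fold is given as at least that size. The 44 control probe sets were left out of all tests, which left 13966, and probe sets with a mean log2 value at or under the 40th percentile were removed, which left 8379. Folds between the parents are differences of group means on this floored log2 scale, and folds for a chromosome are coefficients of the additive model on that scale. Both understate changes of genes near the floor. A fold given as at least a size is always the difference of the group means. Gene symbols came from the platform annotation and were updated through Entrez identifiers to the Release 6 annotation of the genome. Of the 13966 probe sets, 12443 had 1 gene, 327 had several and 1196 had none. Symbols were updated for 12394 of the 12443 and kept as annotated for 49. Chromosome arms and gene lengths came from the same annotation, and no probe sequences were used. A gene with several probe sets is given by the one with the highest mean, and the others are described where they differ in direction or call.

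Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the 8379 probe sets and a threshold of 0.05. All log2 differences and folds compare Z30 with Fr, or the chromosome from Z30 with that from Fr. The parents were compared on their 4 arrays alone (2 residual degrees of freedom). The effect of each chromosome's origin was a term of an additive model of 3 origins over all 10 arrays (5 arrays per origin, 6 residual degrees of freedom). The 3 pairwise interactions were tested together with limma's moderated F test (3 residual degrees of freedom). The position of called genes was tested with two-sided Fisher's exact tests. An origin score was computed for each line and chromosome as a slope through the origin over genes that differed between the parents by more than 1 log2 unit, where 1 is the Z30 level and -1 the Fr level, and scores were compared with a two-sided exact permutation test over the 6 lines. Additivity was measured across genes by correlating the parental difference with the sum of the 3 effects estimated from the 6 lines alone. Of 30 gene lists, 28 had at least 4 measured genes and were tested with camera (preset correlation 0.01) against the 4 effects, with adjustment over the 112 tests. The lists of Turandot stress peptides and heat shock proteins had too few measured genes to be tested.

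These designs, the lists and the rule for naming genes were fixed before the data were examined. The rule names, for the parents and for each chromosome, the 8 called genes with the largest difference in each direction and up to 8 called members of the gene lists, the 5 genes with the smallest p for the interaction, and always the members of the cuticular hydrocarbon list. Mgstl, Bili, CG9676, Clk, cwo, Drsl5, Def, Mtk, shi, Sr-CI and PPO1 are named outside this rule and were chosen after their values were seen.

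After the values were seen, arrays Fr 1 and Z30 1 were found to differ technically from the other 8 arrays, and the limma, camera and position tests were repeated with that array batch as a block. The origin scores, the additivity correlation and the counts over other splits were not blocked. The naming rule was then applied to the blocked calls too. Other alternatives were another scaling, floor, pseudocount, filter or variance model, other sets of arrays or model terms, a camera test with an estimated correlation or on ranks, and leaving out each array in turn.

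The procedure was tested on simulated data with 200 changed probe sets among 8379. For the parental comparison with an array batch in the simulated data and a spread set by signal level, the unblocked fit recovered 0% of 2-fold, 8.47% of 4-fold and 55.2% of 16-fold changes, while the blocked fit recovered 51.5%, 93.9% and 97.0%, with 7.47% of its calls false. When the simulated spread differed between genes, the unblocked fit recovered 42.4% of 16-fold changes and none of the smaller ones, and the blocked fit recovered 0% of 2-fold, 50.0% of 4-fold and 83.1% of 16-fold changes with 1.18% of calls false. In data without a batch, up to 18.3% of the blocked calls were false. For a chromosome effect with a batch in the data, the unblocked fit recovered 35.7% of 2-fold, 83.3% of 4-fold and 98.7% of 16-fold changes with 1.94% of calls false, and the blocked fit 54.5%, 92.8% and 100% with 4.19% false. Apart from the batch, the simulated spread was independent between genes, and no further array stood apart. The simulated shares of false calls therefore do not cover deviations that many genes share on an array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.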

Results

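Head transcript levels were compared between the Drosophila melanogaster strains Fr and Z30 and among 6 lines in which whole chromosomes of one strain had been replaced by those of the other. The parents had 2 arrays each and the lines MMZ, MZM, MZZ, ZMM, ZMZ and ZZM had 1 each, so that each of the 3 large chromosomes came from Z30 on 5 arrays and from Fr on the other 5.

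Arrays Fr 1 and Z30 1 stood apart from the other 8 in ways that did not follow genotype. Their highest signals were 26039 and 28895, against 46285 to 59815 elsewhere, and their bacterial hybridisation controls had geometric mean signals of 651 and 538, against 1500 to 2179. Each parent has 1 array in this batch, so results are also given with the array batch as a block. The MZM array stood apart as well, with a median rank correlation of 0.820 with the other arrays, against 0.890 to 0.915 for the other 7 arrays of the larger batch. On MZM, deviations from a gene's mean fell with gene length across genes (Spearman rho -0.44), and genes of synaptic vesicle release had a median deviation of -1.28 log2 units. Both traits were weaker but present on Fr 1 (rho -0.34, median -0.93) and Z30 1 (rho -0.24, median -0.78).

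**Figure D1:**
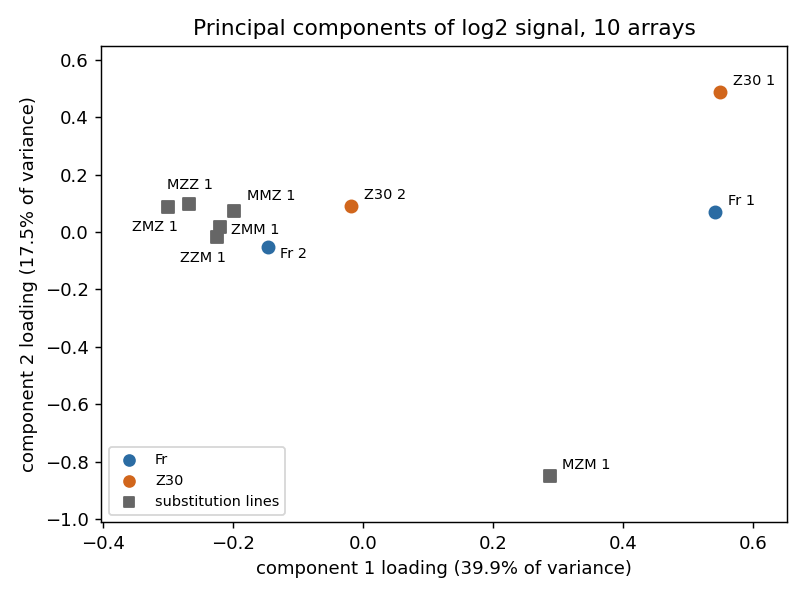
Loadings of the 10 arrays on the leading principal components of log2 signal, with component 1 (39.9% of variance) on the horizontal and component 2 (17.5%) on the vertical axis, both without units, and 1 point per array. Arrays Fr 1 and Z30 1 lie to the right at 0.54 and 0.55 on component 1, and MZM lies lowest at -0.85 on component 2.

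The parents differed most in a few genes of very large effect. Cyp6a17, a cytochrome P450 gene on 2R, had a signal of 10.9 ± 1.48 in Fr and 1440 ± 163 in Z30 (SD, n = 2 each), at least 36.9-fold higher in Z30, since both Fr arrays lay at the floor. smash on 3R, which encodes a LIM domain protein of epithelial cell junctions, was 21.5-fold higher in Z30 (127 ± 5.59 against 2767 ± 514). CG11426 on 3L was 10.3-fold lower in Z30 (5124 ± 33.9 against 502 ± 91.5). All 3 had an adjusted p of 0.0225 in limma and differed in the same direction in both batches. The difference of smash came from 1 of its 4 probe sets, the others having log2 differences of -0.79, 0.57 and 0.99, none of them called. These 3 were the only calls among 8379 probe sets, and 351 had an unadjusted p under 0.05. That is fewer than chance alone gives at this threshold, so the count shows no excess of weaker differences. The same holds for the unblocked counts over all 10 arrays given below for each chromosome and for the interaction. The calls ended without the filter on dim probe sets and without the variance trend (0 calls in limma each, with 646 and 311 at an unadjusted p under 0.05). Without Fr 1, Fr 2, Z30 1 or Z30 2 there were 14, 7, 21 and 42 calls, with these 3 genes called each time.

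With the array batch as a block, limma called 551 probe sets between the parents, 236 higher and 315 lower in Z30. Among those named by the rule and higher in Z30 were the cuticle gene Cpr5C on X (15.4-fold), CG16926 on 2R (9.32-fold), Hf on 2L (8.98-fold), the P450 gene Cyp4ac2 on 2L (6.60-fold), CG7133 on 3L (6.51-fold) and CG17224 on 2L (6.32-fold). Lower in Z30 were the snoRNA host gene Uhg1 on 2R (at least 16.9-fold, with both Z30 arrays at the floor), the chaperone gene Hsc70-2 on 3R (11.2-fold), CG6184 on 3R (9.55-fold), CG7214 on 2L (9.19-fold), the cuticle gene Ccp84Ag on 3R (8.65-fold), CG11414 on 2R (6.29-fold) and the glutathione S-transferase gene GstE14 on 2R (6.27-fold). The blocked standard errors of these 13 genes were 0.28 to 0.50 log2 units and their largest blocked adjusted p was 4.9e-06. On MZM, MZZ and ZZM, the lines with the second chromosome from Z30, CG16926 had 461, 170 and 1849, against 207 to 384 with the Fr one. GstE14 had 267, 368 and 28.8 there, against 104 to 378. Of the 551, 323 differed by more than 2-fold. This fit has 1 residual degree of freedom and takes its spread wholly from the trend over genes. Its standard errors and p-values therefore do not measure a gene's own spread between arrays. Without that trend the block gave 47 calls, 21 higher and 26 lower, which left out Cpr5C (adjusted p = 0.0701) and CG11414 (adjusted p = 0.0862). The blocked fit could not be repeated without a parent array, and without the block leaving out 1 of them also unbalanced the batches, so that the changes that follow hold both array and batch. The difference of CG7214, with Fr signals of 519 and 9027, was -5.26 log2 units without Fr 1 and -1.14 without Fr 2, and -0.00 with its own chromosome in the 6 lines. Cpr5C had 4.95 and 2.95 and Hf 2.56 and 3.77 without Fr 1 and Fr 2, while Hsc70-2 had -4.36 and -2.61 and CG11414 -1.74 and -3.56 without Z30 1 and Z30 2. Within the smaller and the larger batch the differences were -2.62 and -3.78 for CG7214, 2.12 and 5.78 for Cpr5C, 3.64 and 2.70 for Hf, -2.39 and -4.58 for Hsc70-2, and -3.92 and -1.39 for CG11414, which had -0.23 with its own chromosome in the 6 lines.

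Several gene families held members that differed in opposite directions between the parents in the blocked fit. Among 60 cytochrome P450 genes, which encode oxidases of xenobiotics, hormones and lipids, 5 were higher in Z30 and 13 lower, including Cyp6g1, a gene known from insecticide resistance, at 11945 ± 4182 in Fr and 4097 ± 1714 in Z30 (2.96-fold lower, blocked adjusted p = 2.3e-18, or 0.0619 without the trend and 0.698 without the block). In the lines with the second chromosome from Z30, Cyp6g1 had 2593 on MZZ and 3265 on ZZM but 18446 on MZM. The lines with the Fr one had 16500 to 17860. Among 17 odorant-binding protein genes, 2 were higher and 5 lower. Obp56h was 4.16-fold higher in Z30 (743 ± 229 against 3079 ± 860, blocked adjusted p = 2.2e-14). With its own chromosome in the 6 lines Obp56h differed by 0.24 log2 units, with 3071 on ZZM but 832 and 581 on MZM and MZZ. Among 26 glutathione S-transferase genes, 3 were higher and 4 lower, and among 38 cuticle protein genes 3 were higher and 4 lower. Acp1 encodes an adult cuticle protein, although its symbol alone had placed it in the list of male reproduction. It was 4.34-fold lower in Z30, with a log2 difference of -2.61 in the smaller and -1.63 in the larger batch, -0.90 without Z30 1 and -3.33 without Z30 2, and it was higher with its own chromosome from Z30 in the 6 lines. The glial gene nrv2, a sodium pump subunit, was 4.92-fold higher in Z30 (153 ± 39.0 against 741 ± 8.56), and the clock genes Clk and cwo were higher by 1.42 and 1.09 log2 units, though neither was called without the trend (adjusted p = 0.0772 and 0.245). Unblocked, these families held 1 call, Cyp6a17. Adjusted over the list alone without the block, 2 P450 genes were higher and 2 lower, 1 odorant-binding protein gene and 1 cuticle gene were higher and 1 of each lower, 1 transferase gene was higher and 2 lower, and 1 glial gene was higher.

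No list passed camera between the parents without the block. Without Fr 1, Fr 2, Z30 1 or Z30 2 singly 4, 3, 7 and 3 lists passed, 0 without MZM, and 1 without each other line, whose lists enter the same adjustment. With the block, antimicrobial peptides, the inducible defence peptides of the fat body, were shifted up in Z30 (adjusted p = 0.0311, or adjusted p = 0.822 with an estimated correlation). Of the 5 measured, Drsl5, Def and Mtk were called higher by 0.96, 1.04 and 0.54 log2 units, none of them without the trend (adjusted p = 0.208, 0.235 and 0.497), 4 passed when adjusted over the list alone, and all 5 had positive differences. Without MZM in the same family of tests the adjusted p was 0.0778. The list's median deviation was 0.52 on Fr 1 and 0.46 on Z30 1, but -0.65 on Fr 2 and 0.19 on Z30 2. By these medians the shift lay in the larger batch alone. Muscle, hemocyte and nuclear oxidative phosphorylation genes missed the threshold with the block (adjusted p = 0.0563, 0.0563 and 0.0612 in camera), with 4 of 16 muscle genes and 1 of 11 hemocyte genes called lower, and 1 of 59 oxidative phosphorylation genes called higher and 7 lower.

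Of 9 measured genes of cuticular hydrocarbon synthesis, which make the waxes that flies use as pheromones and against drying, 0 were called for the parents or for any chromosome in limma by their brightest probe set, with or without the array batch as a block. Desat2, a fatty acid desaturase known from hydrocarbon differences between populations, had signals of 415 ± 220 in Fr and 409 ± 197 in Z30 (SD, n = 2), and with the third chromosome from Z30, where it lies, its log2 difference was 0.57 ± 0.35 (SE). Desat1, the other desaturase of the pathway on 3R, differed by 0.08 ± 0.27 between the parents and by 0.13 ± 0.15 with the third chromosome. The elongase gene bond, the carboxylase gene ACC, the fatty acid synthase gene FASN1 and the genes Cyt-b5 and ifc had parental log2 differences of -0.13, 0.40, -0.11, -0.01 and 0.27. spidey and Fad2 had 0.58 and 0.74. Adjusted over the list alone, no member passed in any of the 4 effects, with or without the block. The arrays held head RNA only, so these values do not describe hydrocarbon synthesis in other parts of the body. A further ACC probe set had -1.52 ± 0.45 in the blocked parental fit (adjusted p = 0.0145, or 0.430 without the trend), with log2 differences of 0.31 in one batch and -3.36 in the other.

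With the first (X) chromosome from Z30, CG9360 rose 2.68-fold and CG15209 2.24-fold, and Tat, tyrosine aminotransferase, fell 2.90-fold (SE 0.19, 0.15 and 0.20 log2 units, 5 arrays against 5, adjusted p = 0.0203 each in limma). All 3 genes lie on X. Between the parents CG9360 differed by 0.18 log2 units in the smaller and 1.15 in the larger batch, against 1.56 with its own chromosome in the 6 lines. Tat had 3402 ± 563 with the Fr chromosome and 1219 ± 304 with the Z30 one. The other 2 calls, named after their values were seen, were a probe set of Mgstl, a microsomal glutathione S-transferase gene on X (log2 difference -1.32, 8368 ± 377 against 3565 ± 778), and a probe set that has no single gene (2.76-fold lower). Another Mgstl probe set, with a higher mean, was not called. With the array batch as a block there were 9 calls, 4 higher and 5 lower, which held all 5 and added the chaperonin subunit gene CCT2 (3.17-fold higher, 794 ± 159 against 2535 ± 786), the neprilysin gene Nep6 (2.73-fold lower) and Obp18a, an odorant-binding protein gene (2.54-fold lower, 6469 ± 1013 against 2549 ± 551). A further CCT2 probe set had a log2 difference of 0.28 and was not called. The unblocked count of 5, with 207 at an unadjusted p under 0.05, rested on all arrays but Z30 1. It fell to 1 without MZM and to 0 in limma without any of the other 8 arrays singly (145 to 430 at an unadjusted p under 0.05), without the variance trend (212) and within the 8 arrays of the larger batch (275).

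With the second chromosome from Z30, Cyp6a17 rose at least 30.9-fold and Uhg1 fell at least 16.1-fold, so both followed the chromosome that carries them. Cyp6a17 was at the floor on all 5 arrays with the Fr chromosome and had 1407 ± 666 with the Z30 one, while Uhg1 had 659 ± 229 and was at the floor on all 5 with the Z30 chromosome (SD, n = 5, adjusted p = 0.00131 and 9.8e-04 in limma). CG17224 on 2L rose 5.42-fold (304 ± 160 against 1500 ± 329, adjusted p = 0.0132). These 3 were the only calls, with 342 probe sets at an unadjusted p under 0.05. The block gave 13, 10 higher and 3 lower, with all 3 among them. Added genes on chromosome 2 that rose were CG9498 (8.14-fold), nrv2 (3.09-fold), CG17127 (2.98-fold), the chitinase-like growth factor gene Idgf6 (2.22-fold), the ATP synthase subunit gene ATPsynF (2.04-fold), the trehalase gene Treh (1.88-fold) and the ribosomal protein gene RpL37A (1.87-fold). The fold of CG9498 came mainly from the lines, with 44.1 or less for the Fr chromosome and 540 to 715 for the Z30 one, while the Fr parent arrays had 383 and 162 and those of Z30 390 and 473 (6.30-fold by group means). Gpdh1, glycerol-3-phosphate dehydrogenase, fell 2.96-fold (5003 ± 989 against 1711 ± 365, blocked adjusted p = 0.00200) and Reph 2.54-fold. Cyp6a17 had a fitted log2 difference of 5.48 without MZM, against 4.78 with all arrays. The call of CG17224 was lost without Fr 2, Z30 2, MZM or MZZ singly (highest adjusted p = 0.121). Without Fr 1 and without Z30 1 there were 5 and 6 calls, and within the 8 arrays of the larger batch there were 7.

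With the third chromosome from Z30, 2 probe sets rose and 6 fell. smash rose 10.6-fold (318 ± 304 against 2560 ± 333, adjusted p = 0.0483 in limma). The genes that fell were Lsp2, the hexamerin storage protein of the fat body (19.4-fold), Hsc70-2 (16.4-fold, with 3 of 5 Z30-origin arrays at the floor), CG11426 (12.3-fold, 6318 ± 1247 against 522 ± 69.0, adjusted p = 7.3e-06), CG7966 (6.04-fold), the iron regulatory protein gene Irp-1B (2.87-fold) and the glutathione S-transferase gene GstO3 (2.83-fold, 2076 ± 271 against 754 ± 123). A probe set of Bili, named after its values were seen, rose 5.78-fold (135 ± 53.6 against 721 ± 128). Another Bili probe set, with a higher mean, was not called. Lsp2 differed between parents and lines of the same chromosome, and its fold by group means was 13.7. The 3 lines with the Fr chromosome had 23980, 28018 and 27646 and those with the Z30 one 482, 696 and 728, while the Fr parent arrays had 1913 and 8602 and those of Z30 1160 and 2204. The block gave 34 calls, 15 higher and 19 lower, with all 8 among them. Added genes included trx, a chromatin regulator (4.28-fold higher), CG6908 (3.36-fold), GstD9 (2.79-fold), CG42324 (2.77-fold), CG12224 (2.76-fold), CG11353 (2.55-fold) and Dph1 (2.46-fold), all higher, and Ccp84Ag (6.29-fold), CG6912 (5.62-fold), the transcription factor gene zfh1 (3.87-fold) and CG11899 (3.19-fold), all lower. There were 376 at an unadjusted p under 0.05 and 6 calls within the 8 arrays of the larger batch. Leaving out single arrays gave 3 to 9 calls, with 3 without MMZ and 5 without Z30 2, and ended the call of smash without each array but MZM or ZMM, that of Irp-1B without each but Z30 1 or ZZM (highest adjusted p = 0.344 for each), and those of CG7966 and GstO3 without MMZ (adjusted p = 0.0847 for each). The log2 difference of smash was 2.79 without ZZM and 4.03 without ZMM, against 3.40 with all arrays.

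**Figure D2:**
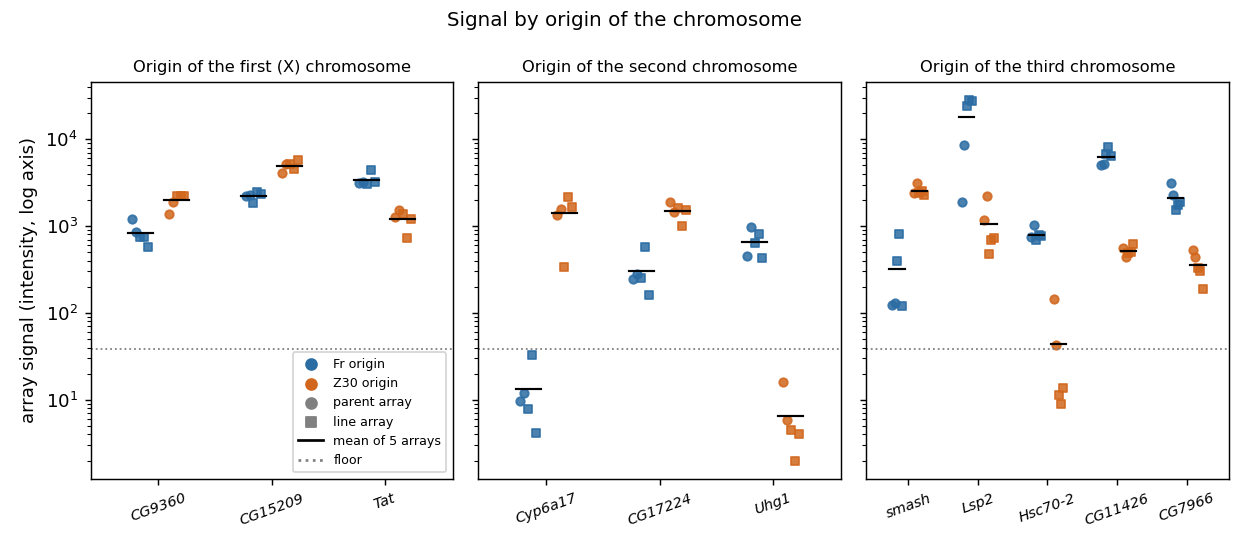
Array signal (intensity, log axis) of the called genes with the largest differences for each chromosome, split by the origin of that chromosome, with circles for parent arrays, squares for line arrays, a bar for the mean of 5 arrays and a dotted line at the floor of 38.9. CG11426 lies at 437 to 614 with the Z30 chromosome and at 5100 to 8086 with the Fr one, and the 2 origins overlap for Lsp2.

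Among the gene lists, synaptic vesicle release genes were shifted up with the first chromosome from Z30 (15 of 15 positive, mean 0.38 log2 units, adjusted p = 0.00865 in camera, or adjusted p = 0.910 with an estimated correlation) and down with the second (15 of 15 negative, mean -0.48, adjusted p = 0.00496, or adjusted p = 0.910 with an estimated correlation). In the 6 lines alone the direction of the second reversed (mean 0.11). No member was called, and the dynamin gene shi had log2 differences of 0.42 ± 0.39 and -0.39 ± 0.39 (SE). Both shifts went with the MZM array, and without it their adjusted p was 0.400 and 0.532. The shift with the first chromosome was also lost without Fr 1, ZMM or ZZM singly (highest adjusted p over single arrays 0.507). Hemocyte genes were shifted down with the second chromosome from Z30 (10 of 11 negative, mean -0.53, adjusted p = 0.00496, or adjusted p = 0.789 with an estimated correlation), with the scavenger receptor gene Sr-CI at -1.73 ± 0.38 and the prophenoloxidase gene PPO1 at -1.16 ± 0.39. No hemocyte gene was called over all genes and 1 was lower when adjusted over the list alone. This shift stayed past the threshold without each array in turn, 0.00335 without MZM and 0.0442 at its highest, and with the block (adjusted p = 0.0143). With the third chromosome from Z30, proteasome genes (23 of 26 negative, mean -0.19, adjusted p = 0.00496) and cytochrome P450 genes (43 of 60 negative, mean -0.14, adjusted p = 0.0386) were shifted down, both with adjusted p = 0.910 with an estimated correlation. On the MZM array, which has the third chromosome from Fr, the medians of these lists stood at 0.44 and 0.34 log2 units, and without it the adjusted p was 0.142 and 0.203. Without MZZ the proteasome shift ended too (mean -0.10), as did the P450 shift without Fr 1, Z30 2 or MZZ (highest adjusted p over single arrays 0.233). No other list passed for a chromosome without the block. With single arrays left out the number of lists ranged from 0 (without MZM) to 7 (without Z30 1) for the first chromosome, from 1 to 7 (without the same arrays) for the second, and from 0 (without MZM or MZZ) to 6 (without Z30 1 or ZZM) for the third. With the block, neurotransmitter receptor genes passed for the first and the third chromosomes (up, adjusted p = 0.0218 each) and muscle genes for the second (down, adjusted p = 0.0456), each with adjusted p = 0.822 with an estimated correlation, and with 0.717, 0.402 and 0.639 when MZM was also left out. Genes of gut digestion, of ovary and egg and of male reproduction passed for no effect, with or without the block.

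Genes that followed a chromosome's origin lay on that chromosome. All 3 called genes of the first chromosome lay on X (Fisher's exact p = 0.00514, 17.3% of 6816 tested genes lie there), all 3 of the second on chromosome 2 (exact p = 0.0564, 38.4% of genes) and all 7 of the third on chromosome 3 (exact p = 0.00301, 43.6% of genes). At an unadjusted p under 0.01 the shares were 42 of 49, 66 of 83 and 87 of 95 (exact p = 1.2e-25, 1.9e-14 and 3.5e-23). With the array batch as a block they were 6 of 6, 12 of 13 and 29 of 29 (exact p = 2.6e-05, 8.4e-05 and 3.4e-11), the exception being CG9676 on X for the second chromosome. Adjusted over these 9 tests the largest p was 0.0564 and the others were 0.00578 or less. The third chromosome test missed the threshold without MMZ (exact p = 0.0831) and without the filter on dim probe sets (exact p = 0.0893, 3 genes), as did the first without that filter (exact p = 0.163, 1 gene). The second passed without Fr 1 (exact p = 0.00829) and without Z30 1 (exact p = 0.00318). Genes are not independent replicates, since neighbours can share an origin effect.

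**Figure D3:**
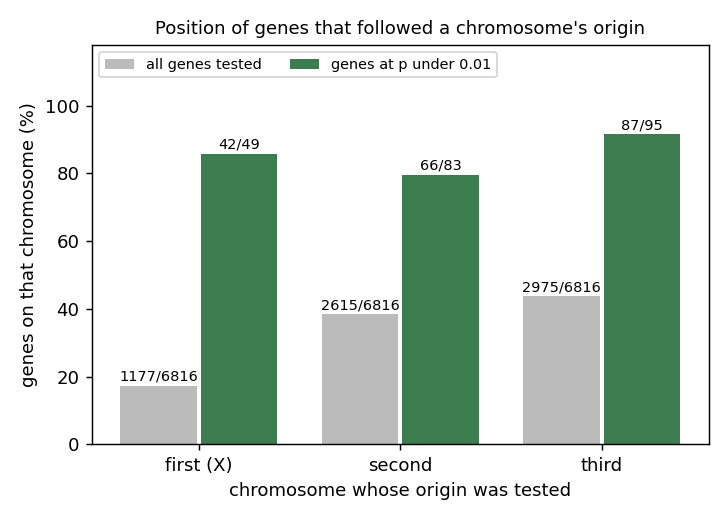
Percentage of genes on the chromosome whose origin was tested, for all genes tested (grey) and for genes with an unadjusted p under 0.01 (green), with counts above the bars, for each of the 3 chromosomes on the horizontal axis. The green bars stand at 85.7%, 79.5% and 91.6% against 17.3%, 38.4% and 43.6% for all genes.

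The lines also followed the labelled origins in part in genes chosen on the parent arrays alone, and those with the Z30 chromosome did not reach the Z30 level. These genes were chosen for a large parental difference on 2 arrays per parent, which can overstate that difference. Scores short of a parent's level can therefore arise from the choice of genes alone. Genes on X that differed between the parents by more than 1 log2 unit (57 genes) had a mean origin score of 0.06 ± 0.24 in the 3 lines with the Z30 chromosome and -0.69 ± 0.07 in the 3 with the Fr one (SD). On chromosome 2 (139 genes) the scores were -0.06 ± 0.42 and -0.89 ± 0.02, and on chromosome 3 (151 genes) 0.13 ± 0.09 and -0.72 ± 0.23. The differences of 0.76, 0.83 and 0.85 each had an exact permutation p of 0.10, the smallest that 3 lines against 3 can give. Scores over genes on the other 2 chromosomes differed by -0.25, -0.20 and -0.37 (exact p = 0.50, 0.30 and 0.40). Their means leaned to Fr for both origins, with -0.51, -0.40 and -0.62 for Z30 and -0.27, -0.20 and -0.25 for Fr. Single lines with the Fr chromosome lay at -0.77 to -0.62 on X, -0.91 to -0.87 on chromosome 2 and -0.90 to -0.46 on chromosome 3, and those with the Z30 one at -0.20 to 0.28, -0.45 to 0.38 and 0.03 to 0.22. MZM had the -0.45 with the Z30 chromosome and the -0.46 with the Fr one. With the parents taken from the larger batch alone, the differences were 0.48, 0.75 and 0.50 (exact p = 0.10 each). Of the genes called between the parents with the block, 50 of 63 on X, 162 of 192 on chromosome 2 and 143 of 201 on chromosome 3 had the parents' sign in the 6 lines for the chromosome they lie on (79.4%, 84.4% and 71.1%), against 38.8% to 68.8% for the other chromosomes. Without single arrays the score differences ranged from 0.19 (X, without Z30 2) to 1.03 (chromosome 2, without MZM). They were 0.25, 0.58 and 0.34 without Fr 1, 0.58, 0.57 and 0.52 without Z30 1, 0.56, 0.42 and 0.60 without Fr 2, and 0.19, 0.46 and 0.37 without Z30 2. Their exact p rose to 0.30 for X and chromosome 3 without Fr 1 and for X without Z30 2, and to 0.40 for chromosome 2 without Fr 2.

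**Figure D4:**
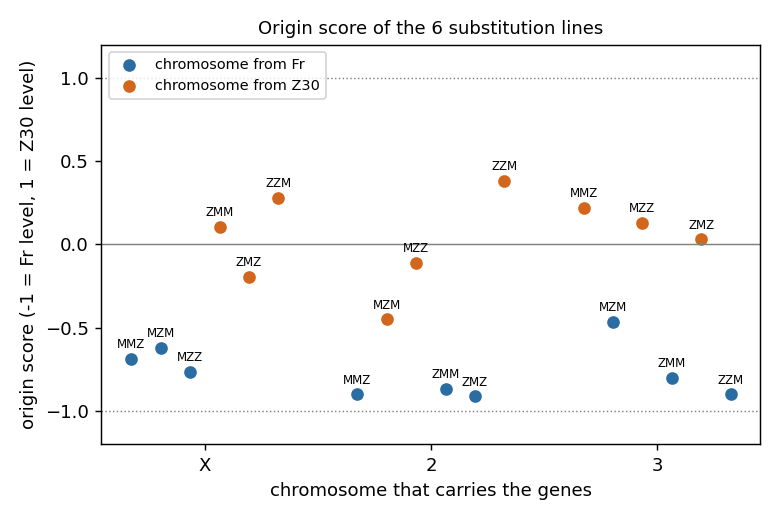
Origin score of each of the 6 lines (vertical axis, no unit, -1 the Fr level and 1 the Z30 level) for genes on X, chromosome 2 and chromosome 3, coloured by the origin of that chromosome, with 1 point per line. On each chromosome the lowest Z30-origin line (-0.20, -0.45 and 0.03) lies above the highest Fr-origin line (-0.62, -0.87 and -0.46).

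Across all genes, the sum of the 3 chromosome effects from the lines was weakly correlated with the parental difference, which was itself weakly reproduced. Between the 2 batches the difference of Z30 and Fr had a correlation of 0.336 (Spearman rho 0.283). Such weak reproduction limits the value that the sum can reach. The limit is not 0.336 itself, since the sum was compared with the mean over both batches. The correlation with the sum across 8379 probe sets, which are not independent replicates, was 0.149 (Pearson, Spearman rho 0.128, slope 0.0598), and over the 551 probe sets called between the parents with the block it was 0.349 (rho 0.317). These 551 were selected on the parental difference itself, which can raise the correlation. Across all probe sets the correlation was 0.348 without Fr 2, 0.240 without Z30 1, 0.0015 without Z30 2 and -0.111 without Fr 1, and within the larger batch it was -0.00047.

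No dependence of one chromosome's effect on the origin of another was called, except with the replicate number as a block. limma's moderated F test of the 3 pairwise interactions gave 0 calls, with 331 probe sets at an unadjusted p under 0.05, and with the array batch as a block 0 calls and 480. With the replicate number as a block, which puts Fr 1 and Z30 1 with the 6 lines, it gave 152 calls and 1866. The 5 smallest p-values belonged to the cyclin gene CycB, CG3857, the clock gene vri, the ribosomal protein gene RpS5b and CG14419 (adjusted p = 0.924 each). Of these, CycB, vri and RpS5b had log2 values of 9.29 to 10.01, 10.23 to 10.96 and 9.24 to 10.17 on the 4 parent arrays and 7.73 to 8.73, 7.78 to 9.93 and 7.80 to 8.31 on the 6 line arrays.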

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

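The tests of the MZM array against gene length and RNA degradation were chosen after the array had been seen to stand apart. Among 130 groups of 5 arrays of named genes, 12 held 1 array far from the other 4, where chance gives about 1 in 20 groups, or 6.5 here. That array was Z30 1 in 6 groups, MZM in 5 and Fr 1 in 1, so all 12 fell on the 3 arrays that stood apart across genes. Nep6, CG17127, RpL37A, CG6912 and CG12224, far on Z30 1 or Fr 1, were named only through calls with the array batch as a block. That choice can favour genes in which these arrays deviate, so the excess over 6.5 may come partly from it.

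The gap of the far array to its nearest neighbour is given as a share of the group's range. On Z30 1, with the chromosome from Z30, Hsc70-2 was highest (143 against 42.5, 0.9319), as were Nep6 (438 against 234, 0.7549) and Irp-1B (805 against 600, 0.7134). RpL37A was lowest there (11690 against 24668, 0.8781), as were CG6912 (68.9 against 168, 0.8695) and CG17127 (350 against 805, 0.8577). On MZM, Tat was highest of the arrays with the first chromosome from Fr (4396 against 3249, 0.8096) and Irp-1B of those with the third from Fr (2980 against 1596, 0.7686). Of the arrays with the second chromosome from Z30, MZM was highest for Cyt-b5 (6264 against 4470, 0.7788) and lowest for Cyp6a17 (340 against 1325, 0.7390) and nrv2 (348 against 735, 0.7123). CG12224 was lowest on Fr 1 among arrays with the third chromosome from Fr (109 against 286, 0.7473).

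Long genes and some gene lists were low on the MZM array, with medians of -1.28 log2 units for synaptic vesicle release, -1.09 for neurotransmitter receptors, -0.98 for the circadian clock and -0.78 for muscle, whereas glutathione S-transferases were high (0.54), so the pattern was not confined to neuronal genes. Other neuronal lists lay nearer 0, with -0.30 for neuropeptides, -0.07 for biogenic amine metabolism and 0.07 for phototransduction. Fr 1 and Z30 1 were low for synaptic vesicle release too (-0.93 and -0.78) and lower still for muscle (-1.36 and -1.32). A trend with gene length (rho -0.44) may account for this and stays open. The first 3 lists were the lowest of 28. Of 100000 random lists matched on length and signal, the medians were -0.29, -0.59 and -0.22, and the 3 lists lay at percentiles 0.073, 0.633 and 0.495. The smallest p against these random lists was 0.00148. It became 0.0414 with allowance for the choice among 28 lists and 0.414 with allowance for 10 arrays too. RNA degradation raises 3' to 5' ratios of control transcripts, and 0 of 3 ratios on MZM lay above those of the other 9 arrays. Its GAPDH and eIF4a ratios, 2.61 and 2.58, lay just under the highest, 2.74 on Z30 2 and 2.61 on Z30 1. Its actin ratio was 1.43, against 1.29 to 1.95 elsewhere, so a milder degradation was not excluded. A difference in the dissected tissue or in the sample may underlie the MZM pattern, and so may the MZM genotype, which had 1 array, so that sample and genotype were not separable.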

How the results depend on the processing

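Alternatives with an array batch block, without Fr 1 and Z30 1 (with or without MZM), with parents from replicate 2 alone, with the blocked gene set for additivity, and the replicate block for the interaction were chosen after seeing the data. Of 92 results on named genes 16 were called, and in 210 further settings of these 148 calls held, 62 were lost and 0 reversed. With single arrays left out, 111 of 160 held, 49 were lost and 0 reversed. Among uncalled ones 48 reversed. The cause was not tested for any change given here. Genes near the floor of 38.9 give understated folds. A correlation over genes called between the parents was not run, with 3 such genes.

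With quantile normalization the second chromosome had 7 calls, 100% on it (exact p = 0.00122), and Cyt-b5 in the parents 0.0535. A pseudocount gave 5 parental calls, an origin score difference of 1.03 for chromosome 3, and 2, 4 and 4 lists for the parents, the first and the second chromosome. Without the filter the parents had 0 calls in limma (646 at an unadjusted p under 0.05) and the 3 chromosomes 2, 1 and 3, with 100% on X (exact p = 0.163) and on chromosome 3 (exact p = 0.0893), score differences of 0.48 (X) and 0.63 (3), and 3, 5 and 4 lists for the parents, the first and the second chromosome. The stricter filter gave 1 call for the second chromosome, a score difference of 1.23 for X, and 2 and 4 lists for the parents and the first chromosome. Without the variance trend the parents and the first chromosome had 0 calls in limma (311 and 212 at an unadjusted p under 0.05).

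A replicate block gave 551 parental calls, 0 for the first chromosome in limma (202 at an unadjusted p under 0.05) and 152 for the interaction. The replicate numbers were not taken as pairing, though the differences between the 2 arrays correlated between strains (r = 0.64). The 6 lines alone gave 0, 0 and 3 calls in limma (736, 342 and 843 at an unadjusted p under 0.05), 100% on chromosome 3 (exact p = 0.0831), 8, 4 and 7 lists, and a mean of 0.11 for synaptic vesicle release with the second chromosome. They reversed uncalled differences of FASN1 (-0.0201) and ACC (-0.104) for the first chromosome, spidey (-0.0498), Cyt-b5 (-0.132), Desat2 (0.0495), ACC (-0.00468) and ifc (-0.0575) for the second, and Fad2 (-0.207) and ACC (-0.0632) for the third. The sum of 3 effects gave Desat2 0.0835 between the parents. Averaged parents gave 0 calls for the first chromosome in limma (235 at an unadjusted p under 0.05), and 3 and 5 lists for the first and the third. Interactions in the model gave 0 and 4 calls for the first and the third in limma (258 and 368 at an unadjusted p under 0.05), with 100% on chromosome 3 (exact p = 0.0831).

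At an unadjusted p under 0.01, 79.5% of genes lay on chromosome 2. A parental difference over 2 log2 units gave scores of 0.96 (X, exact p = 0.20, 4 genes) and 1.19 (3). Genes on the other 2 chromosomes gave -0.25, -0.20 and -0.37. An estimated correlation gave 0, 0 and 0 lists in camera for the 3 chromosomes, and the rank-based test 3, 4, 4 and 4 for the parents and the 3 chromosomes.

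The array batch block gave 551, 9, 13 and 34 calls, 92.3% on chromosome 2, and 1 and 2 lists for the parents and the first chromosome. Without the trend it gave 47 in the parents. Without Fr 1 and Z30 1 there were 0 calls for the first chromosome in limma (275 at an unadjusted p under 0.05) and 7 for the second, 100% on it (exact p = 0.00122), scores of 0.47 (X) and 0.51 (3), additivity of -0.00047, 2, 4 and 4 lists, and first-chromosome differences of Fad2 0.0401 and FASN1 -0.0160. Also without MZM there were 1, 18 and 17 calls, 100% on chromosome 2 (exact p = 5.6e-07), a score of 0.67 (3), 1 and 0 lists for the second and the third, Fad2 0.308 (the first) and ifc 0.0196 (the third). The block without MZM gave 551, 9, 27 and 46 calls, 95.8% on chromosome 2, 1 and 0 lists for the second and the third, Fad2 0.162 (the first), spidey -0.0127 (the second) and FASN1 0.0109 (the third). Parents from replicate 2 alone gave scores of 0.48 (X) and 0.50 (3), and additivity over the 551 was 0.349.

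With each array left out in turn, calls ranged from 3 to 42 for the parents, 0 to 5 for the first chromosome, 2 to 6 for the second, 3 to 9 for the third and 0 to 0 for the interaction. The share on the chromosome was 100% each time (for X it could be tested only without Z30 1). Scores ranged from 0.19 to 0.88, 0.42 to 1.03 and 0.34 to 0.99, additivity from -0.11 to 0.35, and lists from 0 to 7, 0 to 7, 1 to 7 and 0 to 6. A parent left with 1 array was assumed to vary like the other groups. Mean differences ranged from 0.10 to 0.77 (synaptic vesicle release, the first), -0.77 to -0.17 (the second), -0.67 to -0.44 (hemocytes), -0.25 to -0.05 (P450) and -0.22 to -0.10 (proteasome). Uncalled differences that reversed ranged, between the parents, from -0.18 to 0.16 (Cyt-b5), -0.57 to 0.57 (Desat2), -0.28 to 0.0609 (FASN1), -0.33 to 0.0834 (bond) and -0.11 to 0.64 (ifc). For the first chromosome they ranged from -0.27 to 0.18 (Fad2), -0.0783 to 0.15 (FASN1), -0.0708 to 0.12 (ACC) and -0.39 to 0.0528 (ifc). For the second they ranged from -0.0327 to 0.16 (spidey), -0.41 to 0.0717 (Fad2), -0.35 to 0.0720 (Desat2), -0.24 to 0.0674 (FASN1), -0.0748 to 0.0668 (Desat1) and -0.0130 to 0.12 (bond). For the third they ranged from -0.19 to 0.0391 (FASN1) and -0.46 to 0.00799 (ifc).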

Other observations

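The genes and tests on parents against lines, and the test of genes with a higher signal from Z30, were chosen after those patterns had been seen, whereas the counts of other splits and the share of lower signals were planned.

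The 4 parent arrays differed from the 6 line arrays in genes that no chromosome's origin separates. In this design parents against lines is the sum of the 3 pairwise interactions, so the contrast and interaction cannot be told apart. RpS5b and CycB, also among the 5 smallest p-values for the interaction, are therefore not a separate finding here. RpS5b, a ribosomal protein gene, had 839 ± 231 in the parents and 278 ± 40.6 in the lines (SD), the cyclin gene CycB 891 ± 188 and 294 ± 96.7, and CG4278 369 ± 69.1 and 155 ± 24.6. Lower in the parents were the cuticle gene Cpr92F (47.4 ± 33.8 against 308 ± 178), the mitochondrial ribosomal protein gene mRpL43 (214 ± 53.6 against 582 ± 255) and the chitin deacetylase gene Cda4 (318 ± 12.7 against 744 ± 213). With the array batch as a block and the 3 origins in the model, muscle genes (12 of 16 lower, median -0.65, adjusted p = 3.6e-04 in camera), cuticle protein genes (27 of 38, median -0.31, adjusted p = 0.00178) and oxidative phosphorylation genes (48 of 59, median -0.15, adjusted p = 0.00677) were shifted down in the parents. With an estimated correlation the 3 shifts had adjusted p = 0.719, adjusted p = 0.638 and adjusted p = 0.833. The parent arrays were not alike in these lists. Muscle genes had medians of -1.36 on Fr 1, -1.32 on Z30 1 and -0.97 on Z30 2, but -0.13 on Fr 2, against -0.78 to 0.69 on the lines. Cuticle protein genes were low on Fr 2 (-0.12) and Z30 2 (-0.25) but not on Fr 1 (0.30) and Z30 1 (0.37), against -0.05 to 0.32 on the lines. Oxidative phosphorylation genes had -0.31, -0.02, -0.48 and -0.21 on Fr 1, Fr 2, Z30 1 and Z30 2, against -0.19 to 0.29. With the array batch as a block, limma called 0 probe sets between parents and lines, with 668 at an unadjusted p under 0.05.

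Chance was not excluded for this pattern. On every parent array, 195 genes lay above every line array and 145 below, against 39.9 expected in each direction, but 3 and 8 of the 210 splits of the 10 arrays into 4 and 6 gave as many, with up to 425 and 508. Within the larger batch, 403 genes lay higher on both parent arrays than on all 6 lines, and 5 of the 28 splits gave as many, the highest other 853. Ovary RNA in the parents' heads may contribute and cannot be told apart from chance with 2 parent arrays. Over all 10 arrays, 8 germline genes were 0.79 log2 units higher in the parents (exact p = 0.00476, the smallest that 210 splits can give) and 13 eggshell genes 0.56 (exact p = 0.0238), with 2 and 3 of them above the filter on dim probe sets. The fixed ovary and egg list, with 5 genes above that filter, did not pass the blocked camera test of parents against lines. Its median was -0.06, with 3 of 5 members lower in the parents (adjusted p = 0.890 in camera). In the larger batch the germline genes were 0.93 log2 units higher (exact p = 0.0357, the smallest that 28 splits can give) and the eggshell genes 0.14 (exact p = 0.286), and osk had 275 and 258 in the parents against 6.9 to 53.7 in the lines, but 133 on Fr 1 and 29.3 on Z30 1.

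Counts of genes for each chromosome were compared with other splits of the 10 arrays into 5 and 5, of which 98 drawn splits could be fitted. For the first chromosome 2 of 98 splits gave at least the real 5 genes, the real one included. The highest other gave 106, which points to a structure of the samples that was not identified. It had Fr 1, Z30 1 and MZM on one side, but so had 18 of the 98, of which this 1 alone reached the real count. The blocked count was 9. For the second chromosome 2 of 98 gave at least the real 3, the highest other 4, and the blocked count was 13. For the third chromosome 1 of 98 gave the real 8, and the highest other gave 1. By the planned rule, few enough splits gave as many calls for all 3 counts. For the first and the second chromosome another split gave more calls than the real one, so chance was not excluded there. For the third no other drawn split came near the real count, which argues against chance. The splits were not blocked, so the blocked counts were not compared with any.

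More genes were called on the substituted chromosome than elsewhere, and mismatches between Z30 alleles and the array's probes could lower their signals. Among genes at an unadjusted p under 0.01, 57.9% on the substituted chromosome were lower with Z30 (113 of 195, interval 50.7 to 65.0) and 40.6% elsewhere (13 of 32, interval 23.7 to 59.4, Fisher's exact p = 0.0842), so mismatches and regulation cannot be told apart for the lower genes. The 82 genes with a higher signal from Z30 (interval 65.2 to 102, against 33.8 expected by chance) do not follow from mismatches in Z30 alleles. Mismatches in Fr alleles were not tested and stay open for those genes.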
